A study of Rattus norvegicus with 11 samples.

How the data were processed

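RNA of REF52 rat fibroblasts was hybridised to 11 Affymetrix RAE230A arrays after biotin labelling of 6 µg of total RNA, per the labels' protocols. The values deposited by the authors are array signal intensities on a linear scale, 1 per probe set and array; the submitters' processing notes name MAS5 and RMA without saying what each was used for, and their versions are not given in the sources used here. The mean signal after trimming 2% at each end was 500 on every array, and the median log2 value ran from 7.55 to 7.80, a span of 0.25. The number of arrays limits the precision of the comparisons. No detection calls were used here.

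The table holds 15923 probe sets. The 57 control probe sets were left out of the tests, and 15866 were tested. Of these, 12783 have 1 gene symbol in the platform annotation, 312 have several and 2771 have none; only those with 1 symbol were named, and they cover 10411 genes. The annotation was set against a RefSeq gene table (assembly GRCr8), in which 12748 of the 12783 were found; 0 symbols changed. No genome was used here, and no coordinates are given.

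Signals were transformed as log2(signal + 16), without further scaling between arrays, since the array medians spanned less than the limit fixed in advance for it. Fold changes are on this scale, and none is given where a compared array lay near or under the offset, as for Ccne2 on control virus arrays. A linear model with 1 mean for each of the 6 groups was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend). It left 5 residual degrees of freedom, with a prior of 2.88 degrees of freedom and a prior variance of 0.0558. The single deprived control virus array is assumed to vary like the other groups. The 10 comparisons were E2F1 against control virus in each of the 3 media and averaged over them, the differences of the E2F1 effect with LY294002 or in deprivation from that in serum, LY294002 against none in cells with either virus, and deprivation against serum in cells with either virus. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and errors of log2 changes are standard errors from this fit. Without any change in the data, 793.3 probe sets would reach an unadjusted p under 0.05.

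A set of 18 gene lists was tested in each comparison with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 18 lists and 10 comparisons together. Camera with an estimated correlation and fry were run beside it and adjusted in the same way. The lists were G1/S regulators, DNA replication, mitosis, DNA repair and checkpoint, pro-apoptotic, anti-apoptotic, p53 targets, FOXO targets, serum-induced early genes, sterol and fatty acid synthesis, glycolysis and hypoxia, ATF4 targets, ribosome biogenesis, interferon and innate response, matrix and contractile genes, AMP-activated kinase, proteasome, and markers of other cell types. They hold 628 entries, of which 487 were measured, each gene by the probe set with the highest mean over all arrays. With an estimated correlation 0 of the 63 list calls passed.

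The groups, tests, gene lists, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, up to 8 genes with the largest change in each direction among called probe sets with 1 symbol whose compared arrays do not overlap (a condition dropped for the average and the differences), up to 4 called members of each list in each direction or, where none was called, the 2 with the smallest p, and 10 genes named in advance. Of these 10, Ccne1, Apaf1, Prkaa2, Cdkn1a, Fos and Irs2 were measured; E2f1, Cdc6 and Hmgcs1 have no probe set with that single symbol here, and 1 is not reported here. Outside this rule, Mdc1 and a second probe set of Pln were picked after their values were seen, and so were the genes shown in the figures and given as called higher in every medium. Genes with several called probe sets are represented by the brightest. Of 67 named calls with a second probe set of the same gene, 15 (13 genes) had one of the other sign, of which 0 passed the threshold.

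The alternatives were quantile normalization, centring each array on its median, offsets of 1 and 64 in place of 16, leaving out the dimmest 30% of probe sets, eBayes with trend and robust settings, array weights, a replicate block, a fit of the compared groups alone, the mean of all probe sets of a gene for the lists, an estimated correlation in camera, and leaving out each array in turn. After seeing the data, a fit without both second arrays with LY294002 and one with the 3' to 5' difference as a covariate were added. The slope of that covariate comes mainly from the pairs with LY294002, since pairs of the other groups differ by at most 0.045. The steps were tested on simulated data with 200 changed probe sets among 15866: 4-fold changes were recovered in 71% of cases for E2F1 in serum, 73% with LY294002, 55% in deprivation and 87% in the average, and 2-fold changes in 28%, 36%, 5% and 58%. For the difference of the E2F1 effect between LY294002 and serum these shares were 30% and 1%, and for LY294002 in E2F1 cells 63% and 15%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.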

Results

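Transcript levels were measured on 11 Affymetrix rat arrays, each with RNA from REF52 cells, an established rat embryo fibroblast line. Cells grown in 10% serum were held in 0.25% serum for 48 hours and then infected with a control adenovirus (CMV) or with one expressing E2F1, a transcription factor of the cell cycle. They were then kept in deprivation medium or given serum, the latter without or with LY294002, an inhibitor of phosphoinositide 3-kinase. Each combination of virus and medium was measured on 2 arrays, except the deprived control virus cells, which have 1 array. The series title sets the question as how an E2F1-dependent program bears on proliferation and cell death. The number of arrays limits the precision of every comparison. The labels do not say whether arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Array pairs of one group correlated between 0.960 (E2F1 with LY294002) and 0.984 (deprived E2F1 cells) over probe sets. The difference between 3' and 5' control probe sets of GAPDH and beta-actin, a sign of RNA quality, was 0.51 to 0.76 on the log2 scale on the 3 deprived arrays and 0.90 on the second E2F1 array with LY294002. On the other 7 arrays it lay between 0.12 and 0.33. No probe set carries E2f1 as its single symbol in the annotation used, so the level of the introduced gene is not analysed here.

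Averaged over the 3 media, E2F1 raised genes of S phase and mitosis. Ccne2, a cyclin E that partners Cdk2 at S phase entry, rose (log2 change 5.45 ± 0.44, SE, adjusted p = 0.000763), with signals of 2.58 to 95.0 on the 5 control virus arrays and 1372 to 2312 on the 6 E2F1 arrays. Where signals lie this near the offset of 16, its choice sets part of the size of the change, and no fold is given. Its relative Ccne1 rose 8.61-fold (3.11 ± 0.18, adjusted p = 0.000298) and had signals of 1550 to 3236 against 141 to 332. Mki67, the proliferation antigen Ki-67, rose 15.5-fold (3.95 ± 0.40), and Chaf1a, the large subunit of chromatin assembly factor 1, rose as well (3.70 ± 0.29). Brca2, a gene of recombination repair, rose too (3.38 ± 0.14, adjusted p = 8.15e-05). Among the genes that fell most were S1pr3, a sphingosine-1-phosphate receptor (-2.17 ± 0.48, adjusted p = 0.0209), and Klf9, a Krueppel-like factor (-1.97 ± 0.20, adjusted p = 0.00119). Others were Pdgfrb, a receptor for platelet-derived growth factor (-1.90 ± 0.36, adjusted p = 0.0109), and Vldlr, a lipoprotein receptor (-1.80 ± 0.21, adjusted p = 0.00218). In all, limma called 2615 of 15866 probe sets, 1464 higher and 1151 lower, of which 548 and 158 changed at least 2-fold. The count fell to 1540 without the first deprived E2F1 array, 1593 without the first control virus array in serum and 1669 without the first E2F1 array in serum.

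All 28 measured genes of the mitosis list rose with E2F1 in this average, over all probe sets tested and adjusted over the list alone, with a median log2 change of 2.43. Examples are Top2a, the topoisomerase that separates sister chromatids (3.26 ± 0.35), the kinesin Kif20a (3.25 ± 0.57) and the spindle checkpoint kinase Bub1b (3.14 ± 0.41). Of 33 DNA replication genes 28 rose and 0 fell, and 32 rose adjusted over the list alone. Among them are the helicase subunit Mcm6 (2.55 ± 0.27), the primase subunit Prim2 (2.46 ± 0.35) and the polymerase alpha subunit Pola2 (2.43 ± 0.17). Of 10 G1/S regulators 9 rose, and 10 adjusted over the list alone, including the deubiquitinase Usp1 (2.93 ± 0.16) and the transcription factor Mybl2 (2.56 ± 0.21). Of 20 DNA repair and checkpoint genes 10 rose and 1 fell, and 14 rose and 1 fell adjusted over the list alone. Bard1 (2.38 ± 0.28) and its partner Brca1 (1.48 ± 0.22) rose, and Nbn, a subunit of the break-sensing Mre11 complex, fell (-0.47 ± 0.13). Camera with a preset correlation called all 4 lists as higher, with adjusted p between 3.21e-22 (replication) and 2.91e-06 (repair). With an estimated correlation the adjusted p was 0.647 for each of the 4. By fry, which asks only whether a list's genes move one way, the adjusted p was 0.0171 for mitosis, 0.00816 for replication, 0.00545 for G1/S regulators and 0.0171 for repair, and above 0.05 for the matrix (0.0519), ribosome biogenesis (0.101) and sterol lists (0.424). In single media fry gave an adjusted p of 0.0802 for mitosis in serum and in deprivation and 0.101 for repair in deprivation.

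**Figure D1:**
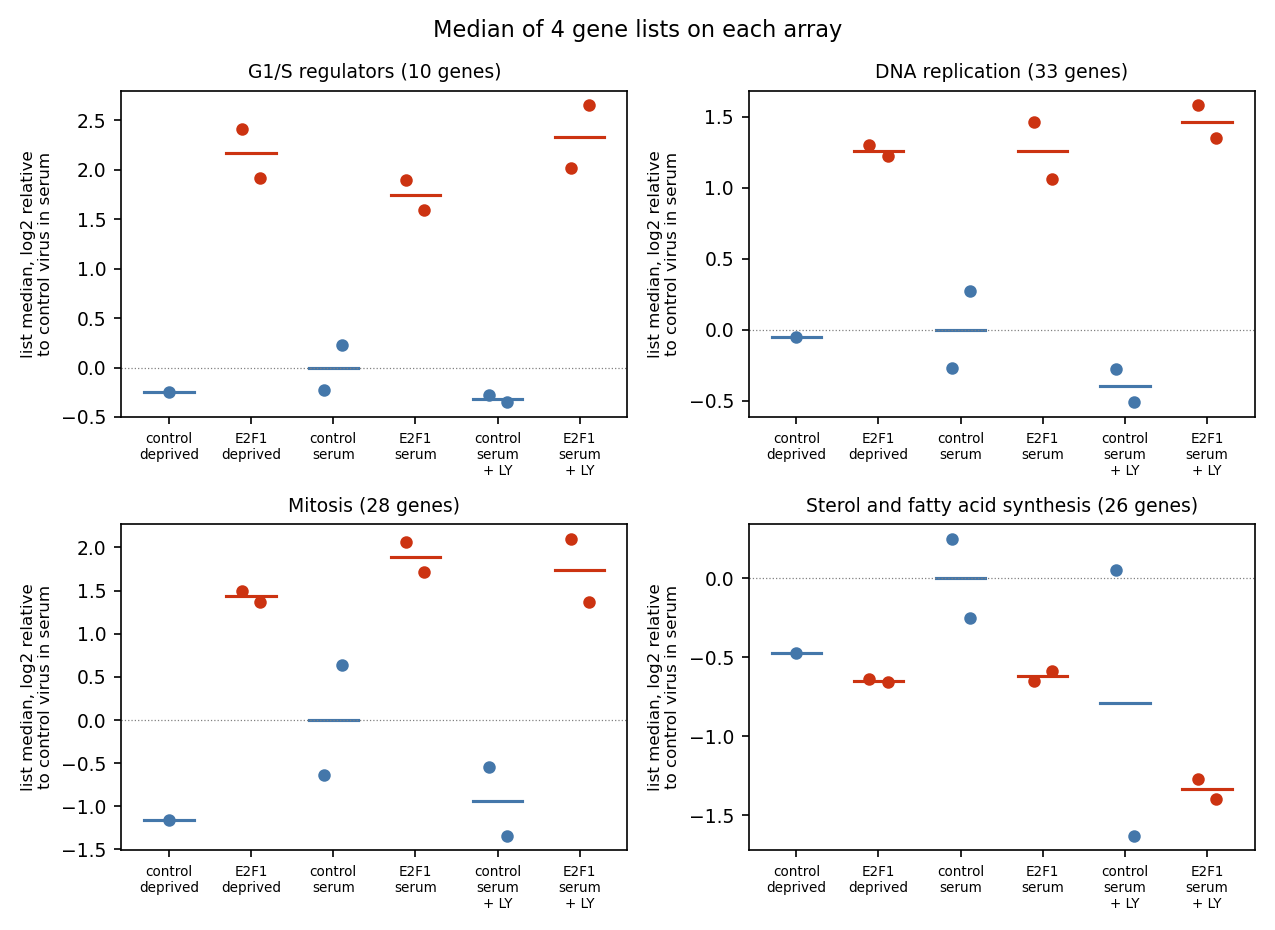
Median level of 4 gene lists on each of the 11 arrays, as log2 relative to the mean of the control virus arrays in serum, by virus (blue control, red E2F1) and medium; points are arrays and lines group means. On the mitosis list the 6 E2F1 arrays lie between 1.37 and 2.10 and the 5 control virus arrays between -1.34 and 0.64; the control virus pair in serum is spread from -0.64 to 0.64, and on the sterol list the control virus pair with LY294002 from -1.63 to 0.05.

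Other lists moved less in the average. Of 37 matrix and contractile genes 12 fell and 1 rose, and 14 fell and 1 rose adjusted over the list alone (median -0.51, camera adjusted p = 0.000883, adjusted p = 0.647 with an estimated correlation). Myl9, a myosin light chain (-1.29 ± 0.22), the actin-binding calponin Cnn1 (-1.22 ± 0.30) and the collagen crosslinker Loxl1 (-1.19 ± 0.29) fell, and the protease inhibitor Timp1 rose (0.76 ± 0.14). Of 32 ribosome biogenesis genes 9 rose and 0 fell, and 13 rose adjusted over the list alone (median 0.22, camera adjusted p = 0.00145, adjusted p = 0.801 with an estimated correlation). Among them are the small nucleolar RNP genes Gar1 (2.16 ± 0.15) and Nop56 (1.34 ± 0.15). Of 26 sterol and fatty acid synthesis genes 4 fell and 1 rose, with the same counts adjusted over the list alone (median -0.52, camera adjusted p = 0.0127, adjusted p = 0.857 with an estimated correlation). The kinases Mvk (-0.94 ± 0.21) and Pmvk (-0.75 ± 0.19) of the mevalonate pathway fell, and the fatty acid synthase Fasn rose (0.73 ± 0.19). This sterol call was lost without the first control virus array with LY294002, where the median was -0.27 and the adjusted p 0.123.

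Apoptosis genes moved both ways. Of 32 pro-apoptotic genes 2 rose and 4 fell, the same as adjusted over the list alone (median -0.07, camera adjusted p = 0.427). The mitochondrial nuclease Endog (0.44 ± 0.12) and the Bcl2 relative Bok (0.46 ± 0.12) rose, and the BH3-type genes Bnip3 (-0.87 ± 0.14) and Bad (-0.64 ± 0.11) fell. Apaf1, the apoptosome scaffold, stood at -0.03 ± 0.16 (adjusted p = 0.942). Of 19 anti-apoptotic genes 2 rose and 2 fell, also adjusted over the list alone, with Bag1 at 1.03 ± 0.18 and Bag3 at -0.78 ± 0.10 (camera adjusted p = 0.977). Of 19 p53 targets 5 rose and 3 fell, and 8 rose and 3 fell adjusted over the list alone (median 0.31, camera adjusted p = 0.102). The p53 inhibitors Ppm1d (1.08 ± 0.16) and Mdm2 (1.05 ± 0.20) and the Cdk inhibitor Cdkn1a (0.88 ± 0.14, adjusted p = 0.00593) rose, while the DNA damage binding protein Ddb2 fell (-0.88 ± 0.23). Of 31 FOXO targets 2 rose and 6 fell, and 3 rose and 7 fell adjusted over the list alone (median -0.20, camera adjusted p = 0.135). The Cdk inhibitor Cdkn1b rose (1.25 ± 0.27) and the pyruvate dehydrogenase kinase Pdk2 fell (-1.33 ± 0.20). Of 33 interferon and innate response genes 6 rose and 1 fell, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.234). Those that rose include the immunoproteasome subunit Psmb9 (2.93 ± 0.24, adjusted p = 0.00084) and the peptide transporters Tap1 (1.94 ± 0.20) and Tap2 (1.16 ± 0.30). Of 10 genes of the AMP-activated kinase list 2 rose, also adjusted over the list alone (camera adjusted p = 0.234). They are its catalytic subunits Prkaa2 (1.23 ± 0.24, adjusted p = 0.0116) and Prkaa1 (1.13 ± 0.16, adjusted p = 0.00392).

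Camera called none of the remaining 5 lists in the average. Of 36 serum-induced early genes 6 rose and 3 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.962), with Atf3 at 1.51 ± 0.42 and Junb at -0.65 ± 0.11. Fos did not pass the test (-1.82 ± 0.52, adjusted p = 0.0518). Of 29 glycolysis and hypoxia genes 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.977), with the oxygen sensor Egln1 up (1.48 ± 0.19) and the haem oxygenase Hmox1 down (-0.96 ± 0.25). Of 33 ATF4 targets 7 rose and 2 fell (10 and 3 adjusted over the list alone, adjusted p = 0.46), with the amino acid transporter Slc7a1 at 1.51 ± 0.18. Of 29 proteasome genes 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0595), with the activator subunit Psme1 at 0.89 ± 0.14. Of 29 markers of other cell types 2 rose and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.927). They are the endothelial receptors Kdr (0.63 ± 0.12) and Tie1 (0.47 ± 0.13) and the leukocyte marker Ptprc (-0.68 ± 0.19). Signals were 5.19 to 42.7 for Kdr, 11.9 to 54.0 for Tie1 and 3.19 to 51.9 for Ptprc. These lie near the offset of 16, and array medians ran from 172 to 207. No detection calls were used, so whether these genes were expressed is not known. The median was below 0 and camera's sign above it for the anti-apoptotic, early, glycolysis and ATF4 lists, and the mean was above 0 for the early and ATF4 lists. A second probe set of Egln1, Ptprc, Akt1, Eef2k, Foxo3 or Pfkfb3 went the other way by value without passing the test.

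In serum alone the genes that rose with E2F1 again include genes of S phase and repair. Ccne2 (log2 change 4.97 ± 0.71, adjusted p = 0.0457, 2 arrays against 2), Brca2 (3.52 ± 0.23, adjusted p = 0.00487) and Bard1 (3.05 ± 0.44, adjusted p = 0.0457) rose. Ube2t, a ubiquitin-conjugating enzyme of the Fanconi pathway, rose 7.73-fold (2.95 ± 0.22, adjusted p = 0.00487). Ccne1 rose 5.65-fold (2.50 ± 0.29, adjusted p = 0.0402). The neuropeptide gene Nmu fell (-2.70 ± 0.39, adjusted p = 0.0457), as did Klf9 (-2.28 ± 0.32) and the stromal marker Cd248 (-1.73 ± 0.26). A second probe set of Klf9 (0.11) and of Cd248 (0.29) did not pass the test and had the other sign. Limma called 56 probe sets, 46 higher and 10 lower. Over all probe sets tested, 3 of 33 replication genes, 3 of 10 G1/S regulators, 1 of 28 mitosis genes and 2 of 20 repair genes rose. Adjusted over the list alone 28, 8, 28 and 8 rose, with 0 down in each. Their medians were 1.31, 1.74, 1.87 and 0.73. Camera gave adjusted p of 4.91e-20, 2.52e-08, 3.61e-17 and 2.39e-05, against an adjusted p of 0.647 with an estimated correlation for each. Fen1, the flap nuclease (2.29 ± 0.31), Pola2 (1.86 ± 0.28), the phosphatase Cdc25b (1.97 ± 0.27) and Usp1 (2.09 ± 0.26) are examples. Of 26 sterol and fatty acid synthesis genes 24 lay below 0, with Mvk at -1.22 ± 0.34, and 0 passed, also adjusted over the list alone (median -0.68, camera adjusted p = 0.000303, adjusted p = 0.806 with an estimated correlation). Of 32 ribosome biogenesis genes 1 rose (Gar1, 1.86 ± 0.25), and 3 adjusted over the list alone (median 0.27, camera adjusted p = 0.00237, adjusted p = 0.801 with an estimated correlation). Camera calls of FOXO targets (-0.23, adjusted p = 0.035), interferon genes (0.43, adjusted p = 0.0207) and matrix genes (-0.33, adjusted p = 0.0134) had adjusted p of 0.79, 0.801 and 0.79 with an estimated correlation. The FOXO call was lost without the first control virus array (-0.17) or the second E2F1 array in serum (-0.18), the interferon call without the second control virus array (0.26) or the first E2F1 array in serum (0.33), and the matrix call without the latter (-0.25).

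The count of 56 in serum was unchanged without the deprived control virus array. Without the second control virus array in serum most of these 56 calls were lost, and other probe sets were called in their place. Without any other single array nearly all of them were lost, and a fit of the compared groups alone called 0.

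With LY294002 present, E2F1 raised Ccne2 (6.08 ± 0.71, adjusted p = 0.00839, 2 arrays against 2), the kinesin Kif18b (4.84 ± 0.78), the spindle protein Tacc3 (3.83 ± 0.79) and Psmb9 (3.83 ± 0.39, adjusted p = 0.00663). Mki67 rose 21.0-fold (4.39 ± 0.64), Ccne1 13.6-fold (3.77 ± 0.29, adjusted p = 0.00318) and Cdkn1a 2.29-fold (1.20 ± 0.23, adjusted p = 0.0298). The growth factor Tgfb3 (-2.60 ± 0.34, adjusted p = 0.0126), the coagulation receptor F3 (-2.27 ± 0.41) and Vldlr (-2.20 ± 0.34) fell. So did Myl9 (-2.07 ± 0.35) and the ubiquitin ligase scaffold Cul4a (-2.07 ± 0.23, adjusted p = 0.00786). Limma called 858 probe sets, 600 higher and 258 lower, 489 and 146 of them by at least 2-fold. Of the replication, G1/S, mitosis and repair lists, 26 of 33, 8 of 10, 21 of 28 and 6 of 20 genes rose and 0 fell. Adjusted over the list alone 32, 10, 28 and 9 rose. Their medians were 1.81, 2.60, 2.77 and 0.85, with camera adjusted p of 2.27e-24, 1e-11, 1.22e-20 and 6.42e-06 and an adjusted p of 0.647 with an estimated correlation for each. Of 37 matrix and contractile genes 5 fell and 1 rose, and 11 fell and 1 rose adjusted over the list alone (median -0.61, camera adjusted p = 0.000488, adjusted p = 0.647 with an estimated correlation). The smooth muscle actin Acta2 (-1.22 ± 0.24) and the matrix glycoprotein Sparc (-1.02 ± 0.22) fell. Of 33 ATF4 targets 5 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.0746), among them the serine synthesis enzyme Psat1 (1.72 ± 0.37) and the pseudokinase Trib3 (1.43 ± 0.31). Of 26 sterol and fatty acid synthesis genes 1 fell (Acly, the citrate lyase, -0.85 ± 0.20), and 0 adjusted over the list alone (median -0.71, camera adjusted p = 0.00606, adjusted p = 0.844 with an estimated correlation). Without the first control virus array with LY294002 that median was 0.10. Of 32 ribosome biogenesis genes 4 rose, and 6 adjusted over the list alone (median 0.29, camera adjusted p = 0.00581, adjusted p = 0.828 with an estimated correlation), a call lost without the same array (0.04).

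On the second E2F1 array with LY294002 the 3' to 5' difference was 0.90, and without that array limma called 192 probe sets in place of 858. It called 270 and 321 without the first or second control virus array with LY294002, 273 without either deprived E2F1 array, 477 without either control virus array in serum and 504 without either E2F1 array in serum. The count was 0 without both second arrays with LY294002 and in a fit of the compared groups alone.

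In deprivation medium E2F1 raised Kif18b (5.56 ± 0.96, adjusted p = 0.0314), Ccne2 (5.29 ± 0.87), the kinetochore gene Spc24 (4.53 ± 0.58) and, by 31.0-fold, Mki67 (4.95 ± 0.79), on 2 arrays against 1. Prkaa2, the alpha 2 catalytic subunit of AMP-activated kinase, rose (2.56 ± 0.47, adjusted p = 0.0359), from a signal of 20.0 on the control virus array to 241 and 160 on the E2F1 arrays. In serum its change was 0.01 ± 0.38 (adjusted p = 0.996), and the test of the difference between these media gave 2.56 ± 0.60 (adjusted p = 0.348). Eln, which encodes elastin, fell 8.67-fold (-3.12 ± 0.54, adjusted p = 0.0314), and so did the skeletal muscle actin Acta1 (-2.47 ± 0.24, adjusted p = 0.0158) and the mitochondrial carboxykinase Pck2 (-2.74 ± 0.56, adjusted p = 0.0479). Eln and Acta1 stand apart on the 1 deprived control virus array (signals of 1624 and 120), against at most 207 and 32.2 on the other 10 arrays. Limma called 456 probe sets, 348 higher and 108 lower, 337 and 102 of them by at least 2-fold. Of the replication, G1/S, mitosis and repair lists, 15 of 33, 6 of 10, 7 of 28 and 2 of 20 genes rose and 0 fell. Adjusted over the list alone 25, 9, 25 and 4 rose. Their medians were 1.56, 2.44, 2.42 and 0.59, with camera adjusted p of 2.83e-17, 4.87e-10, 3.61e-17 and 0.00021 and an adjusted p of 0.647 with an estimated correlation for each. Of 19 p53 targets 1 rose and 0 fell, and 8 rose and 3 fell adjusted over the list alone (median 0.66, camera adjusted p = 0.00606, adjusted p = 0.647 with an estimated correlation), with the lysosomal gene Dram1 at 1.33 ± 0.26. Of 29 proteasome genes 1 rose (Psmd8, 1.02 ± 0.20), also adjusted over the list alone (median 0.14, camera adjusted p = 0.0134, adjusted p = 0.801 with an estimated correlation). Ribosome biogenesis (median 0.14, 1 up) and matrix genes (-0.47, 1 down) had camera adjusted p of 0.0153 and 0.0264, and adjusted p of 0.828 and 0.798 with an estimated correlation. The matrix call was lost without the first deprived E2F1 array (-0.37) and with quantile normalization (-0.23, adjusted p = 0.203), the ribosome call with quantile normalization (adjusted p = 0.0694) and the replicate block (0.09, adjusted p = 0.0649), and the proteasome call with the 3' to 5' difference as a covariate (0.11, adjusted p = 0.0711).

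The 3' to 5' differences of the 3 deprived arrays (0.51, 0.56 and 0.76) were above those of the 4 arrays in serum without LY294002 (0.12 to 0.19), and the median change of all probe sets was -0.14 for E2F1 in deprivation. The count of 456 was 0 without either deprived E2F1 array and in a fit of the compared groups alone, 121 without either E2F1 array in serum and 237 without either control virus array in serum.

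**Figure D2:**
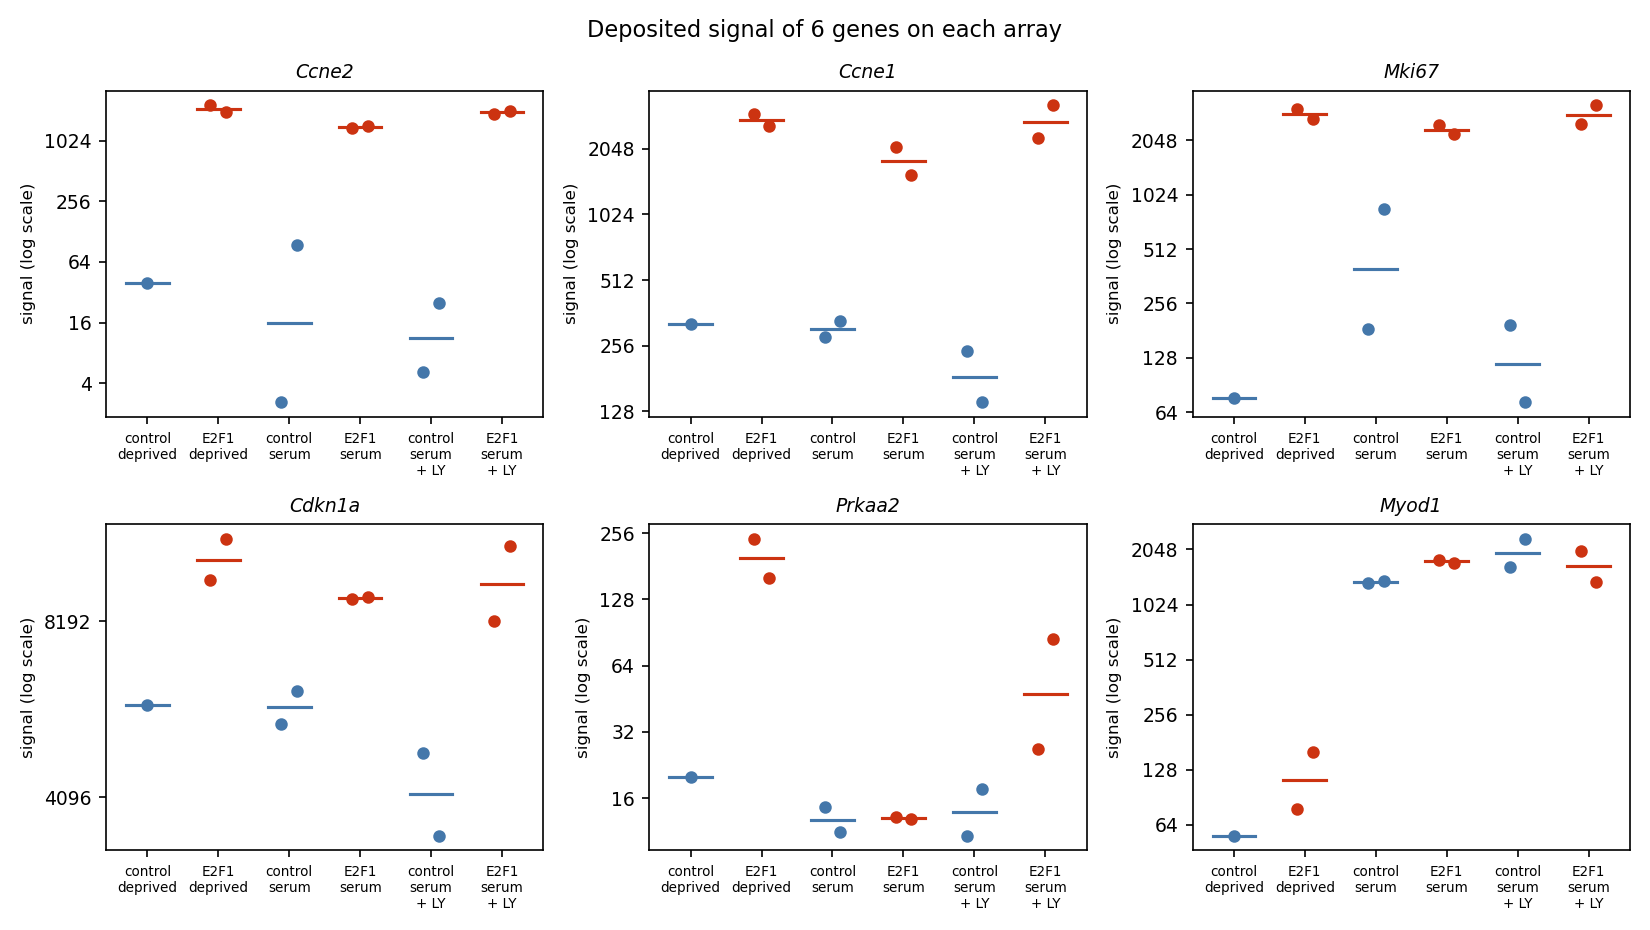
Deposited signal of Ccne2, Ccne1, Mki67, Cdkn1a, Prkaa2 and Myod1 on each array, on a log2-scaled axis, by medium and virus (blue control, red E2F1); points are arrays and lines geometric means. Ccne1 lies between 1550 and 3236 on the E2F1 arrays and at or below 332 on the control virus arrays, while Myod1 lies at or below 160 on the 3 deprived arrays and at or above 1342 on the other 8.

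The calls in the 3 media could be compared directly, since they share no array. Of the probe sets called higher, 41 were shared by serum and LY294002 (1.74 expected of independent lists, Fisher's exact test, adjusted p = 2.9e-53) and 39 by serum and deprivation (1.01 expected, adjusted p = 3.24e-58). LY294002 and deprivation shared 229 (13.2 expected, adjusted p = 2.42e-252). Of those called lower, 3, 1 and 17 were shared (0.163, 0.0681 and 1.76 expected, adjusted p = 0.000563, 0.066 and 2.54e-12). The 39 called higher in every medium include Ccne1, Ccne2, Brca2, Fen1, Pola1, Pola2, Cdc25b, Usp1 and the checkpoint adaptor Mdc1, and 0 were called lower in every medium. One variance per probe set served all 3 comparisons, which favours the same probe sets in each. These overlaps changed when single arrays were left out, where each array of a pair also takes 1 of the 5 residual degrees of freedom. Without the second control virus array in serum, serum shared more higher calls with LY294002 and with deprivation, though most of its reported calls had been replaced by others. Without the first one it shared 1 and 1, without the first E2F1 array in serum 0 and 0, without the second 1 and 1, without either deprived E2F1 array 3 and 0, and without any 1 array with LY294002 3 and 3. The 229 became 0 without either deprived E2F1 array, 73 without either E2F1 array in serum, 98 without the second E2F1 array with LY294002, 122 and 125 without the first or second control virus array with LY294002 and 150 without either control virus array in serum. The 17 lower calls became 0, 5, 7, 8, 15 and 2 in that order, and 28 without the first E2F1 array with LY294002. The 3 lower calls shared by serum and LY294002 became 0 without any 1 of these arrays. The 1 shared by serum and deprivation became 2 without the second control virus array in serum, stayed 1 without either control virus array with LY294002 and became 0 without any other.

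**Figure D3:**
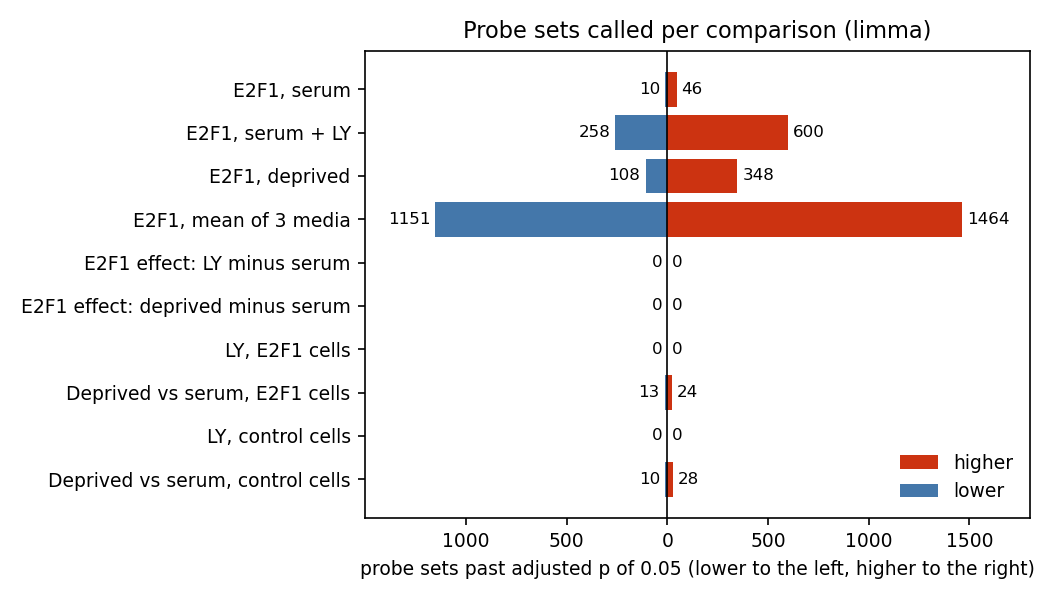
Number of probe sets called by limma at an adjusted p under 0.05 in each of the 10 comparisons, higher to the right and lower to the left. The averaged E2F1 effect has 1464 higher and 1151 lower, and 4 comparisons have 0.

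Tests of whether the E2F1 effect differed between media called 0 probe sets. For LY294002 against serum limma found 998 probe sets at an unadjusted p under 0.05 against 793.3 expected (smallest adjusted p = 0.23), and for deprivation against serum 1542 (smallest adjusted p = 0.122). Camera called the effect on G1/S regulators (median difference 0.83, adjusted p = 9.54e-06), replication (0.49, adjusted p = 2.06e-07) and mitosis genes (0.81, adjusted p = 1.54e-05) as larger with LY294002 than in serum, with adjusted p of 0.647, 0.79 and 0.801 with an estimated correlation. The members of these lists named here were Pola2 (1.89 ± 0.39, adjusted p = 0.568), Usp1 (1.18 ± 0.37, adjusted p = 0.735) and Ccne1 (1.27 ± 0.41, adjusted p = 0.741), and 0 members passed over all probe sets tested, and 1 replication gene adjusted over the list alone. The mitosis call was lost without the second control virus array in serum (0.04, adjusted p = 0.43), where replication stood at 0.15 (adjusted p = 0.0354) and G1/S regulators at 0.48. For deprivation against serum camera called p53 targets as higher (median difference 0.56, adjusted p = 0.0118, adjusted p = 0.647 with an estimated correlation), with the stress gene Sesn1 at 0.90 ± 0.34 and Ddb2 at -1.69 ± 0.59, neither past the threshold. With the 3' to 5' difference as a covariate, whose slope comes mainly from the pairs with LY294002, the p53 median was 0.33 (adjusted p = 0.0621).

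For LY294002 itself limma called 0 probe sets in E2F1 cells (1769 at an unadjusted p under 0.05, smallest adjusted p = 0.126) and 0 in control virus cells (1050, smallest adjusted p = 0.199), against 793.3 expected. In the simulated data the comparison in E2F1 cells recovered 63% of 4-fold and 15% of 2-fold changes, so 0 calls does not mean no change. By list, sterol and fatty acid synthesis genes were lower with the inhibitor in cells with either virus. In E2F1 cells 3 of 26 lay above 0 (median -0.73, camera adjusted p = 0.000111, adjusted p = 0.801 with an estimated correlation), with the desaturase Scd2 at -2.84 ± 0.73 and the sterol regulator Insig2 at -0.72 ± 0.17. In control virus cells 1 of 26 lay above 0 (median -0.73, camera adjusted p = 1.77e-06, adjusted p = 0.798 with an estimated correlation), but the list stood at 0.05 on the first array with LY294002 and at -1.63 on the second, and its median change was 0.05 without the second. FOXO targets, which Akt signalling represses, were higher in E2F1 cells with the inhibitor (22 of 31 above 0, median 0.32, camera adjusted p = 0.00491, adjusted p = 0.647 with an estimated correlation), with Txnip, an inhibitor of thioredoxin, at 1.81 ± 0.52. That call was lost without the second E2F1 array with LY294002 (median 0.05, adjusted p = 0.171), where the 3' to 5' difference was 0.90, and with that difference as a covariate (0.06, adjusted p = 0.62). Matrix and contractile genes were lower in E2F1 cells (6 of 37 above 0, median -0.49, camera adjusted p = 2.91e-05, adjusted p = 0.647 with an estimated correlation), with collagen Col1a1 at -1.27 ± 0.35. In control virus cells early genes were higher (27 of 36 above 0, median 0.50, camera adjusted p = 1.02e-05, adjusted p = 0.647 with an estimated correlation), with Junb at 0.81 ± 0.18. Mitosis genes were lower there (2 of 28 above 0, median -0.94, camera adjusted p = 1.63e-09, adjusted p = 0.79 with an estimated correlation), a call lost without the second control virus array in serum (-0.32, adjusted p = 0.111). Replication (-0.36, adjusted p = 2.22e-05), G1/S (-0.30, adjusted p = 0.012), repair (-0.21, adjusted p = 0.0182) and ATF4 genes (-0.31, adjusted p = 0.0026) were called lower as well, with adjusted p of 0.647 to 0.801 with an estimated correlation. All 4 calls were lost without that array (0.01, -0.07, -0.05 and -0.20), the G1/S call also without the first control virus array with LY294002 (-0.35) and the repair call without the first (-0.24) or second (-0.12). In E2F1 cells G1/S (0.44, adjusted p = 0.00288), replication (0.27, adjusted p = 0.0266) and AMP-activated kinase genes (0.19, adjusted p = 0.0367) were called higher, with adjusted p of 0.79, 0.865 and 0.647 with an estimated correlation. The G1/S call was lost with the 3' to 5' difference as a covariate (0.36, adjusted p = 0.0822) and without both second arrays with LY294002 (0.35, adjusted p = 0.057). The replication call was lost without the second E2F1 array in serum (0.02) or the first with LY294002 (0.14), and the kinase call without the first (0.26) or second (0.26) E2F1 array with LY294002, the second E2F1 array in serum (0.20) or the first control virus array with LY294002 (0.19). Without the first E2F1 array with LY294002 limma called 325 probe sets in E2F1 cells, and without the first control virus array with LY294002 it called 10 in control virus cells.

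Deprived cells differed from cells in serum in single genes. Myod1, the myogenic transcription factor, was 13.8-fold lower in deprived E2F1 cells (-3.79 ± 0.33, adjusted p = 0.0138) and 19.1-fold lower in deprived control virus cells (-4.26 ± 0.40, adjusted p = 0.0191), with signals of 55.8 to 160 on the 3 deprived arrays and 1342 to 2342 on the other 8. Phospholamban (Pln), a regulator of the muscle calcium pump, was higher in both by the same probe set (2.88 ± 0.22, adjusted p = 0.0133, and 3.33 ± 0.27, adjusted p = 0.0135). Its brighter probe set was called in E2F1 cells (2.61 ± 0.33, adjusted p = 0.0413) and had 2.31 ± 0.40 in control virus cells (adjusted p = 0.0822). In E2F1 cells Prkaa2 rose (2.88 ± 0.38, adjusted p = 0.0443) and the Notch ligand Jag1 rose 6.80-fold (2.77 ± 0.22, adjusted p = 0.0133), and the cyclooxygenase Ptgs1 fell 5.48-fold (-2.46 ± 0.32, adjusted p = 0.0413). In control virus cells Eln rose 15.6-fold (3.96 ± 0.54, adjusted p = 0.0444), the growth factor Bmp4 rose 5.25-fold (2.39 ± 0.21), and the natriuretic peptide receptor Npr3 (3.75 ± 0.50) and Acta1 (2.58 ± 0.24) rose. The neurofilament gene Nefh fell 11.2-fold (-3.49 ± 0.20, adjusted p = 0.00231). The rises of Eln and Acta1 rest on that 1 deprived array, where both stand apart from the other 10. Limma called 37 probe sets in E2F1 cells (24 higher, 13 lower) and 38 in control virus cells (28 higher, 10 lower), the latter resting on 1 deprived array.

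Among the lists, mitosis genes were lower in deprivation, with 2 of 28 above 0 in control virus cells (median -1.16, camera adjusted p = 4.8e-07, adjusted p = 0.798 with an estimated correlation) and 2 of 28 in E2F1 cells (-0.56, adjusted p = 0.0367, adjusted p = 0.871 with an estimated correlation). The call in E2F1 cells was lost without either deprived E2F1 array (-0.59 and -0.56), the first E2F1 array in serum (-0.33) or the first E2F1 array with LY294002 (-0.56), and with the replicate block (adjusted p = 0.0627), an offset of 1 (adjusted p = 0.0727) or the mean of all probe sets of a gene (adjusted p = 0.0646). Proteasome genes were lower in control virus cells, where 1 of 29 lay above 0 (median -0.33, camera adjusted p = 3.29e-06, adjusted p = 0.647 with an estimated correlation), and matrix and contractile genes were higher (29 of 37 above 0, median 0.38, adjusted p = 0.012, adjusted p = 0.79 with an estimated correlation). Both rest on the 1 deprived control virus array, where the markers of other cell types also stood at 0.28 relative to control virus arrays in serum. With the 3' to 5' difference as a covariate, chosen after the data were seen, limma called 3 probe sets in E2F1 cells and 0 in control virus cells. The mitosis medians were then -0.12 and -0.08. With group means fitted, the slope of this covariate comes only from differences within array pairs. These were 0.635 and 0.141 with LY294002 and at most 0.045 in the other groups. The fit thus carries a slope set by arrays with LY294002 over to deprivation, and does not tell whether RNA quality matters there. The sterol list was called lower in control virus cells (-0.47, adjusted p = 0.026, adjusted p = 0.865 with an estimated correlation), a call lost without the first control virus array in serum (-0.19) and with the covariate (-0.07, adjusted p = 0.779). In E2F1 cells the count was 0 without either E2F1 array in deprivation or in serum, 2 without either control virus array in serum, 18 without either control virus array with LY294002 and 408 without either E2F1 array with LY294002. In control virus cells it was 1 without the first and 0 without the second control virus array in serum, 2 without either deprived E2F1 array, 5 without either E2F1 array in serum and 64 without either E2F1 array with LY294002, and a fit of the compared groups alone called 0 in both.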

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

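The tests on the level and on the spread of the control virus arrays were chosen only after the result was seen. The prediction of the test on RNA quality was written before, but both fits that it uses were added only after the data were seen.

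Lists were marked because the E2F1 effect differed between media by camera's test of the difference itself. For LY294002 against serum the median differences were 0.83 for G1/S regulators, 0.49 for DNA replication and 0.81 for mitosis. The early genes differed by -0.29, a call lost without the first control virus array in serum (-0.20), the second control virus array with LY294002 (-0.16), the second E2F1 array in serum (-0.27) or the first E2F1 array with LY294002 (-0.17). The ATF4 targets differed by 0.24, lost without the second control virus array in serum (0.14), the second control virus array with LY294002 (0.18), the first E2F1 array in serum (0.18) or the first E2F1 array with LY294002 (0.17). The matrix and contractile genes differed by -0.29, lost without the second control virus array in serum (-0.26), the first control virus array with LY294002 (-0.10), the second E2F1 array in serum (-0.17) or the second E2F1 array with LY294002 (-0.09). The matrix call was also lost with the 3' to 5' difference as a covariate (-0.10), and the ATF4 call with quantile normalization (0.20), without the dimmest 30% (0.20) and with the mean of all probe sets of a gene (0.16). With an estimated correlation the adjusted p of these 6 lists lay between 0.647 and 0.801.

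For deprivation against serum the median differences were 0.36 for G1/S regulators, 0.49 for mitosis, 0.56 for p53 targets, 0.49 for sterol and fatty acid synthesis and 0.12 for the proteasome. For DNA replication the median was -0.006, while the mean was 0.20 and camera called it higher. Without the second control virus array in serum the replication (-0.24), mitosis (-0.20), G1/S (0.19) and proteasome (0.04) calls were lost, the first 2 with the other sign. The replication call was also lost without the first deprived E2F1 array (-0.06), the second E2F1 array in serum (-0.16), the first control virus array with LY294002 or the first E2F1 array with LY294002 (both -0.006), and the mitosis call without the second E2F1 array in serum (0.33). The sterol call was lost without the first control virus array in serum (0.14), the second deprived E2F1 array (0.42) or the first E2F1 array in serum (0.52). With the 3' to 5' difference as a covariate, which is raised on the deprived arrays, the calls of replication (0.08, adjusted p = 0.143), mitosis (0.08, adjusted p = 0.335), p53 targets (0.33, adjusted p = 0.0621), sterol (0.23, adjusted p = 0.267) and proteasome genes (0.06, adjusted p = 0.0928) were lost. The slope of that covariate comes mainly from the pairs with LY294002, so these losses do not tell whether RNA quality matters in deprivation. With an estimated correlation the adjusted p of the 6 lists called for deprivation against serum lay between 0.647 and 0.865.

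The larger E2F1 effect on cell cycle lists with LY294002 was weighed further. Lower RNA quality of the second arrays with LY294002 is argued against, but only weakly. The lowest median difference of the 3 lists was 0.473 with both arrays left out or with the 3' to 5' difference as a covariate. Leaving both out leaves 1 array with LY294002 per virus, and the slope of the covariate comes mainly from the pairs with LY294002. Spread between the control virus arrays in serum may account for the mitosis and replication lists, which fell to 0.037 and 0.151 without the second of them, and the G1/S list at 0.484 leaves this open for that list. A lower level in control virus cells with LY294002 (mitosis median change -0.938) cannot be told apart from it, because both are measured against the same pair of serum arrays. On the mitosis list the E2F1 arrays stood at 2.06 and 1.72 in serum and at 2.1 and 1.37 with LY294002. The larger difference for mitosis thus came from the control virus arrays and not from a higher level in E2F1 cells. For replication the E2F1 arrays stood at 1.46 and 1.06 against 1.58 and 1.35. For G1/S regulators they stood at 1.9 and 1.59 against 2.02 and 2.65. An action of the inhibitor on the E2F1 response otherwise stays open and was not tested in another way.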

How the results depend on the processing

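The fits with the 3' to 5' covariate and without both second arrays with LY294002 were chosen only after the results were seen. Of 532 comparisons of named genes 0 turned in sign under any alternative while past the threshold with or without it. Of 244 past the threshold, 232 stayed past it under quantile normalization, 148 with an offset of 1 and 148 with the replicate block. Of 63 list calls, 35 were kept without any single array, 54 under both scaling alternatives and 0 with an estimated correlation, and 18 were lost or turned with the covariate. The counts of called probe sets in single media moved widely. Leaving out either array of a pair outside the comparison gave the same count, because either one takes the same residual from the shared variance. How far such losses of residual degrees of freedom account for the moves was not tested.

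The averaged E2F1 count of 2615 stayed between 2217 and 3194 under the alternatives and between 1540 and 3067 without single arrays. The other counts, with 56 (E2F1 in serum), 858 (with LY294002), 456 (deprived), 37 (deprivation in E2F1 cells) and 38 (in control virus cells) as reported, moved by over 1.5 times as follows. With the replicate block they were 3 in serum, 131 deprived, 6 in E2F1 cells and 3 in control virus cells. Deviations of same-numbered arrays correlated between -0.02 and 0.07, except 0.30 for both groups with LY294002. Little shared deviation by number was thus seen outside LY294002, but the labels do not say whether the numbers pair the arrays. Quantile normalization gave 97 in E2F1 cells, and median centring 37 in serum and 91 in E2F1 cells. An offset of 1 gave 5, 449, 190, 16 and 20 in the order above, and an offset of 64 gave 807 deprived and 126 in E2F1 cells. Without the dimmest 30% they were 157, 1311, 774 and 133 for the first 4, and with trend and robust settings 101 in serum, 697 deprived and 72 in E2F1 cells. Array weights gave 522, 51, 1223, 1173 and 112, and a fit of the compared groups alone 0 for each. Without both second arrays with LY294002 they were 2, 0, 1094, 966 and 189, and with the covariate 286 with LY294002, 965 deprived, 3 in E2F1 cells and 0 in control virus cells.

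Of the calls shared between E2F1 comparisons, the 229 higher with LY294002 and in deprivation became 76 with the replicate block, 48 with array weights, 97 with an offset of 1, 130 with the covariate and 0 without both second arrays with LY294002, but 392 without the dimmest 30%, 361 with an offset of 64 and 344 with trend and robust settings. The 41 and 39 that serum shared with these became 3 and 3 with the block, 4 and 4 with an offset of 1, 26 and 23 with median centring, 0 and 1 without both second arrays, 42 and 232 with array weights, 120 and 110 without the dimmest 30% and 79 and 71 with trend and robust settings. The 17 lower calls shared by LY294002 and deprivation ran from 0 without both second arrays or with array weights to 85 with an offset of 64, the 3 of serum and LY294002 from 0 to 18 and the 1 of serum and deprivation from 0 to 40.

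Leaving out 1 array gave 0 to 71 calls for E2F1 in serum, 192 to 1190 with LY294002, 0 to 662 deprived, 0 to 408 for deprivation in E2F1 cells and 0 to 64 in control virus cells. It gave 0 to 325 for LY294002 in E2F1 cells, 0 to 10 for LY294002 in control virus cells and 0 to 1 for both differences of the E2F1 effect, all 0 by limma as reported.

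Further list calls ended under alternatives. With the covariate these were the sterol (-0.51) and ribosome lists (0.15) for E2F1 with LY294002, the kinase (0.25) and G1/S lists (0.36) for LY294002 in E2F1 cells, repair (-0.10) for LY294002 in control virus cells, and early genes (0.10) in deprived E2F1 cells. Without both second arrays with LY294002 the kinase (0.26), FOXO (0.05) and G1/S calls (0.35) in E2F1 cells ended, and mitosis (-0.56) in deprived E2F1 cells. Quantile normalization ended replication for LY294002 in E2F1 cells (0.21), the proteasome (0.07), replication (0.09) and sterol calls (0.51) of the difference between deprivation and serum, and median centring the FOXO call in serum (-0.32) and the early genes in deprived E2F1 cells (0.40).

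Some list medians turned. The E2F1 difference between deprivation and serum ran from -0.24 to 0.39 for replication and from -0.20 to 1.23 for mitosis, low without the second and high without the first control virus array in serum. The sterol list under E2F1 with LY294002 ran from -1.34 to 0.10 without the second or first control virus array with LY294002. For LY294002 in control virus cells it ran from -1.63 without the first to 0.045 without the second, and was 0.045 without both second arrays. The early genes in deprived control virus cells had a median of 0.28 with the covariate, with camera's sign turned.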

Other observations

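Tests of a swap between groups, of RNA quality behind the sterol list and of the score on deprived arrays were chosen only after the result was seen, and the chance splits, the inhibitor score and the test on the second arrays before.

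Genes outside the fixed lists were also called. Asf1b, a histone chaperone, rose 10.0-fold in the average (3.33 ± 0.30, adjusted p = 0.000908) and Espl1, the separase that opens cohesin at anaphase, 11.3-fold (3.50 ± 0.39, adjusted p = 0.00181). In serum the lamin gene Lmnb2 rose 6.13-fold (2.62 ± 0.28, adjusted p = 0.0387) and the chromatin ATPase Atad2 6.79-fold (2.76 ± 0.34, adjusted p = 0.0402). In deprivation the polycomb gene Cbx2 (4.49 ± 0.55, adjusted p = 0.0211) and Mxd3, a Max-binding repressor (4.24 ± 0.45, adjusted p = 0.017), rose. Genes that fell include Nkain4, which binds the sodium pump (-3.11 ± 0.62 with LY294002, adjusted p = 0.0326), and the xenobiotic oxidase Cyp1b1 (-1.46 ± 0.20 in serum, adjusted p = 0.0457).

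In deprived E2F1 cells, early genes lay above their level in serum E2F1 cells by a median of 0.29 (22 of 36 above 0, camera adjusted p = 0.0302, adjusted p = 0.801 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone. That call was lost without the first control virus array with LY294002 (0.29), the first deprived E2F1 array (0.15) or the first E2F1 array in serum (0.19). In control virus cells the same list stood at 0.43 (26 of 36 above 0, camera adjusted p = 0.0056, adjusted p = 0.798 with an estimated correlation), with 4 higher and 1 lower adjusted over the list alone and 0 over all probe sets tested. With the 3' to 5' difference as a covariate, which is raised on the deprived arrays, both calls were lost (0.10, adjusted p = 0.847, and 0.28, adjusted p = 0.958, with camera's sign turned in the latter), and median centring ended the call in E2F1 cells (0.40, adjusted p = 0.0829). The slope of that covariate comes mainly from the pairs with LY294002, so its result does not tell whether RNA quality matters in deprivation. The AP-1 gene Fosb stood at 2.01 ± 0.43 (adjusted p = 0.0941) in E2F1 cells and 3.05 ± 0.53 (adjusted p = 0.0816) in control virus cells. Klf15, a glucocorticoid and FOXO responsive factor, was 3.70-fold higher in deprived than in serum control virus cells (1.89 ± 0.26, adjusted p = 0.0444) and fell with E2F1 in deprivation (-1.53 ± 0.26, adjusted p = 0.0305). These values share the single deprived control virus array.

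Of 100 splits of the virus labels within media, 1, the real one, gave as many calls as the averaged E2F1 comparison. It gave 2615, against at most 12 in the other splits. This argues against chance for the averaged E2F1 count but does not exclude it. Most other splits put arrays of both viruses into one group, which raises the residual spread and by itself lowers their counts.

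The sterol and fatty acid list stood at 0.05 on the first control virus array with LY294002 and at -1.63 on the second, relative to control virus arrays in serum, and at -1.27 and -1.40 on the E2F1 arrays with LY294002. A swap with a serum array is argued against, since the lower control virus array in serum stood only 0.49 below the higher (-0.49). RNA quality (3' to 5' difference 0.33 on the second array, 0.19 on the first), cells on the first array that did not respond to the inhibitor, and a wrong label cannot be told apart. On RNA quality, the deprived arrays had larger differences (0.51 to 0.76) and list medians of only -0.47 to -0.66, and the first E2F1 array with LY294002 was at -1.27 with a difference of 0.26, which speaks against it but compares other media and the other virus. On a missing response, a score was taken over the 100 genes moved most each way by the inhibitor in E2F1 cells. It was -0.04 on the first control virus array with LY294002, next to the control virus serum arrays (-0.03 and 0.03), whose mean is the reference. The prediction written before took a score within the range of these serum arrays as a sign of a missing response or a wrong label. The second control virus array with LY294002 scored 0.27, further from the first than the serum arrays lie from each other. A check added after the result was seen found scores of 0.13 on the deprived control virus array and 0.6 and 0.61 on the deprived E2F1 arrays. The score thus also moves without inhibitor and does not decide the question. The early genes stood at 0.27 on the first control virus array with LY294002 and at -0.06 and 0.06 on the control virus serum arrays. No biological explanation was tested.

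Deviations of the second arrays with LY294002 from their group means correlated across probe sets (0.30), where genes are not independent replicates. With 2 arrays in a group the first deviates equally in the other direction, so the correlation does not tell which arrays stand apart. The 3' to 5' differences of the second arrays were 0.33 and 0.90, against 0.19 and 0.26 on the first arrays. Whether RNA quality may be the source cannot be told apart from other causes, because pairs of the other groups differ by at most 0.045 and give no slope to adjust with. No biological explanation was tested.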
